A study of Schizosaccharomyces pombe with 30 samples.

How the data were processed

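RNA of Schizosaccharomyces pombe mutants was compared with wild-type RNA on an Agilent splicing array, with 30 arrays in 10 groups of 3. Per the labels, the mutant RNA carried Cy5 and the wild-type RNA Cy3 on every array, so there is no dye swap, and wild-type RNA has no arrays of its own. The labels' protocols state that cells grew in YES5 medium at 30 °C to mid-log phase, that shifts to 37 °C lasted 2 hours and shifts to 16 °C lasted 9 hours, and that total RNA was taken with hot acid phenol. The groups were pht1∆ at 30 and 16 °C, swr1∆ at 30 and 37 °C, usp107DAmP at 30 °C, prp16DAmP at 16 and 37 °C, and the double mutants pht1∆ usp107DAmP at 30 °C, pht1∆ prp16DAmP at 16 °C and swr1∆ prp16DAmP at 37 °C. DAmP alleles are made to lower the abundance of an mRNA by disturbing its 3′ end.

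The deposited values are log ratios within each array and were read as log2 of mutant over wild type, with the direction taken from the dyes in the labels. The base of the logarithm is not given in the sources used here. The lowest value, −5.53, excludes base 10 for a scanner's range (the highest is 4.38), but natural logarithms are not excluded, in which case every log2 value printed would be larger by a constant factor. The limma p-values would not change then, but results that use a cut-off on the log2 scale (at least 1.5-fold, or an exon feature within 0.1 of 0) would. Scanner software, background correction, normalization within arrays and the summary of probes are not given in the sources used here, and signal over background was not available for the tests. Medians of the arrays lay within 0.0254 of 0 over all features, so the arrays look centred. The table held 14556 features of 5081 genes, comprising 5069 exon, 4836 intron and 4651 junction features, with 0 missing values. Each gene had at most 1 exon feature. Some intron values occurred repeatedly within an array, covering 35.9% of intron features on pht1∆ 30 °C replicate 1, 21.7% on swr1∆ 30 °C replicate 1, and 0.331 to 7.98% on the other arrays.

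A splicing index was computed for 4821 introns of 2315 genes as the log ratio of the intron feature minus that of the exon feature of the same gene. A positive index is the direction that retention of an intron gives, and it also arises where an exon feature falls and its intron feature does not follow. The 15 introns without an exon feature were left out. Transcript level was the log ratio of the exon feature in 5069 genes. Gene names came from the annotation of assembly ASM294v3, in which 4806 genes matched by locus tag and 200 by synonym, 75 did not match and 4214 had a symbol. The build behind the array design is not given in the sources used here, so no coordinates are printed. Introns were given annotated lengths and splice sites only in genes whose highest intron number equals the annotated number of introns, which placed 4333 introns. Identity therefore rests on the order of introns, and probe sequences were not used here.

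Each comparison was made with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) over all 30 arrays, with 1 mean per group, two-sided tests, Benjamini-Hochberg adjustment over introns or genes, and an adjusted p of 0.05. All p-values written as adjusted p for introns and genes are from limma, each error after ± is its standard error unless SD is written, and each group has n = 3 arrays. Comparisons with wild type test the mean log ratio against 0, so that a dye bias and the spread of the wild-type RNA are part of the result. Both cancel in a difference between mutant groups, if they are constant. An interaction is the double mutant minus both of its single mutants, and it keeps minus 1 times any shared offset. The labels do not say whether replicates are cultures or repeated hybridisations, and the p-values measure only the spread between arrays. Per-array medians were compared by exact two-sided permutation tests, in which 3 against 3 arrays cannot go below p = 0.1.

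Strength of the 5′ splice site was scored over 6 bases against 5060 annotated coding introns, of which 27.5% carry the commonest site. The branch site was the best 5-base match in the last 60 bases. Introns of at least 30 bases were scored and split into tertiles (33.33% each) of each property, and shares of introns with a called, higher index were compared between the outer tertiles by Fisher's exact test, adjusted over 46 tests, or over 4 tests where introns of genes with a flat exon feature (within 0.1 of 0) were compared with all introns. The distance from branch site to 3′ splice site, the restriction to flat exon features and the tests of called introns were chosen after the data were seen. Introns of a gene share an exon feature and are not independent.

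Gene lists were tested with camera (inter-gene correlation 0.01), with Benjamini-Hochberg adjustment over 362 tests. An estimated correlation was the alternative. Tests with fry ask another question, whether a list changed at all and not whether it changed more than other genes or introns, so intron lists may pass it through the index being above 0 over all introns. With features on the array, the lists held 15 genes of the SWR complex, 11 histones, 141 ribosomal proteins, 79 spliceosome genes, 24 heat shock, 22 core stress, 144 meiosis, 22 mating, 18 subtelomere, 51 chromosome segregation, 9 phosphate, and 23 tubulin and microtubule genes. Lists needed at least 3 features. The groups, comparisons, lists, alternatives and the rule for named genes were fixed before the data were examined. By that rule the targeted genes come in every group. Introns and genes follow in order of size among those that passed with the same sign on all 3 arrays (without overlap, for differences between groups), which is also what rose or fell most refers to, up to 10 of each sign for pht1∆ and swr1∆ at 30 °C and the double mutants against wild type, up to 5 for other comparisons with wild type, doubles against singles and interactions, and up to 3 elsewhere. Passing list members come last, at most 4 per list and comparison.

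Same-numbered replicates were checked for shared deviations from their group means. The numbers pair the arrays (every r above 0.1) for pht1∆ usp107DAmP and usp107DAmP (r = 0.48, 0.42 and 0.58), for pht1∆ prp16DAmP and prp16DAmP at 16 °C (0.22, 0.29 and 0.18), and for swr1∆ and pht1∆ at 30 °C (0.37, 0.46 and 0.10), from the data and not the labels. Alternatives were arrays centred or scaled to equal spread, junction or exon and junction features as the reference, intron features alone, fits on only the groups compared, a robust and trended prior, replicate blocks, a change of at least 1.5-fold, a split of introns at the median, means in place of medians, and each array left out in turn. Added after the data were seen were a block within paired groups, leaving out both arrays with the most repeated values, leaving out introns with repeated values, adding to interactions the mean of the 7 other groups or of those without a deletion, and turning the sign of the swr1∆ 37 °C arrays.

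Simulations with 200 changed features tested the fits for index changes of log2 0.5 and 1. Recovered were 58.2% and 100% in pht1∆ at 30 °C, and 23.9% and 86.6% for pht1∆ usp107DAmP against pht1∆. The interaction at 16 °C gave 8.96% and 68.7%. Of all calls 7.03%, 5.41% and 3.28% were false. Real arrays differ in spread, so these rates may not hold. Simulated differences of 0.05 between tertiles of 4320 introns were recovered as 0.048. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for tables, exact tests and figures.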

Results

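Splicing and transcript levels were measured on 30 two-colour splicing arrays, in 10 groups of 3, each array setting RNA of a mutant against wild-type RNA. Pht1 is the H2A.Z histone variant of fission yeast, Swr1 the ATPase that places it in chromatin, Usp107 a component of the U1 snRNP, and Prp16 an ATPase of the second step of splicing. The splicing index of 4821 introns and the transcript level of 5069 genes are given as log2 of mutant over wild type. The number of arrays limits the precision. Between replicates, the index correlated across introns with r from 0.404 to 0.437 in pht1∆ at 30 °C, from 0.566 to 0.647 in pht1∆ at 16 °C, and from 0.0398 to 0.756 in swr1∆ prp16DAmP at 37 °C, the lowest and the highest of all groups. Introns are not independent replicates in these correlations. The spread of values was smallest at 37 °C, with a mean SD over all features of 0.169 in swr1∆, 0.138 in prp16DAmP and 0.198 in the double mutant, against 0.259 to 0.383 in the other groups.

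The targeted genes were examined before any other. The pht1 feature fell by 0.65 ± 0.10 in pht1∆ at 30 °C (adjusted p = 2.6e-05, arrays from −1.08 to −0.43) and by 0.74 ± 0.10 at 16 °C (adjusted p = 5.3e-06, arrays from −0.83 to −0.65). In the arrays labelled pht1∆ usp107DAmP it was 0.02 (−0.07 to 0.08) and in those labelled pht1∆ prp16DAmP −0.03 (−0.16 to 0.12), neither called. The differences from the single mutant were 0.67 ± 0.14 (adjusted p = 0.00123) and 0.71 ± 0.14 (adjusted p = 0.00143), so pht1 does not bear out the label of either double mutant, and both are named by their labels only. The swr1 feature was −0.11 in swr1∆ at 30 °C (adjusted p = 0.620), −0.19 at 37 °C (adjusted p = 0.538) and −0.11 in swr1∆ prp16DAmP (adjusted p = 0.787). That feature may lie outside the deleted part and then checks nothing, so swr1∆ groups are named by their labels only. The usp107 feature was −0.01 in usp107DAmP (adjusted p = 0.982) and −0.11 in its double mutant. The prp16 feature was −0.15 in prp16DAmP at 16 °C (adjusted p = 0.656), −0.19 at 37 °C, 0.28 in pht1∆ prp16DAmP and −0.01 in swr1∆ prp16DAmP. None of these values of usp107 and prp16 passed, so the arrays do not bear out the DAmP labels either, and these groups too are named by their labels only. It fell in a group not labelled for it, pht1∆ usp107DAmP (−0.51 ± 0.20, adjusted p = 0.0395, arrays from −1.20 to 0.08), and was −0.46 in swr1∆ at 37 °C (adjusted p = 0.359) and −0.20 to 0.02 in the other groups. In groups not labelled for them no other target passed, with pht1 at −0.10 to 0.17, swr1 at −0.26 to 0.22 and usp107 at −0.15 to 0.21.

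To ask what loss of H2A.Z does to splicing at 30 °C, pht1∆ was compared with wild type. The index of intron 1 of bud20, which encodes a factor of the large ribosomal subunit's assembly, rose by 3.78 ± 0.25 (13.8-fold, adjusted p = 7.7e-12), with the intron feature up by 3.05 and the exon feature at −0.73. Intron 1 of mfm2, a gene for the M-factor mating pheromone, followed with 2.85 ± 0.25 (4.4e-09), but there the exon feature fell by 2.87 and the intron feature was −0.02. Intron 1 of SPAC186.08c (2.42 ± 0.20), intron 1 of the meiotic recombination gene rec7 (2.24 ± 0.33), intron 8 of ers1, a factor of RNAi heterochromatin (2.20 ± 0.22), and intron 1 of rpc82, an RNA polymerase III subunit (2.09 ± 0.15), came next. In SPAC186.08c and ers1 the exon feature was −0.03 and 0.02. Of the negative indices, intron 1 of hpz1 fell by 1.63 ± 0.15 while its exon feature rose to 1.79, intron 2 of SPBC3E7.11c fell by 1.21 ± 0.15, intron 2 of elg1, a factor of DNA replication, by 1.10 ± 0.17 (exon feature 0.10), and introns 6, 4, 5 and 2 of rsd1 by 1.19, 1.08, 1.03 and 0.96 with a shared exon feature at 1.12. With junction features as the reference, hpz1 turned to 0.75.

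In pht1∆ at 30 °C, 673 introns had a higher and 174 a lower index, of 4821, in 625 genes. The called introns came largely from genes whose transcript fell. Of 599 called introns with an exon feature below −0.1, 98.0% were higher, of 96 with a flat exon feature 70.8% (95% exact binomial interval 60.7 to 79.7), and of 152 with an exon feature above 0.1 11.8%. In 30.5% of the higher introns the intron feature moved more than the exon feature, and their medians were 0.16 and −0.38. The count of calls was 526 without replicate 1 and 547 without replicate 3. With arrays scaled to equal spread it was 386, and with only the 3 arrays of the group 286.

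**Figure D1:**
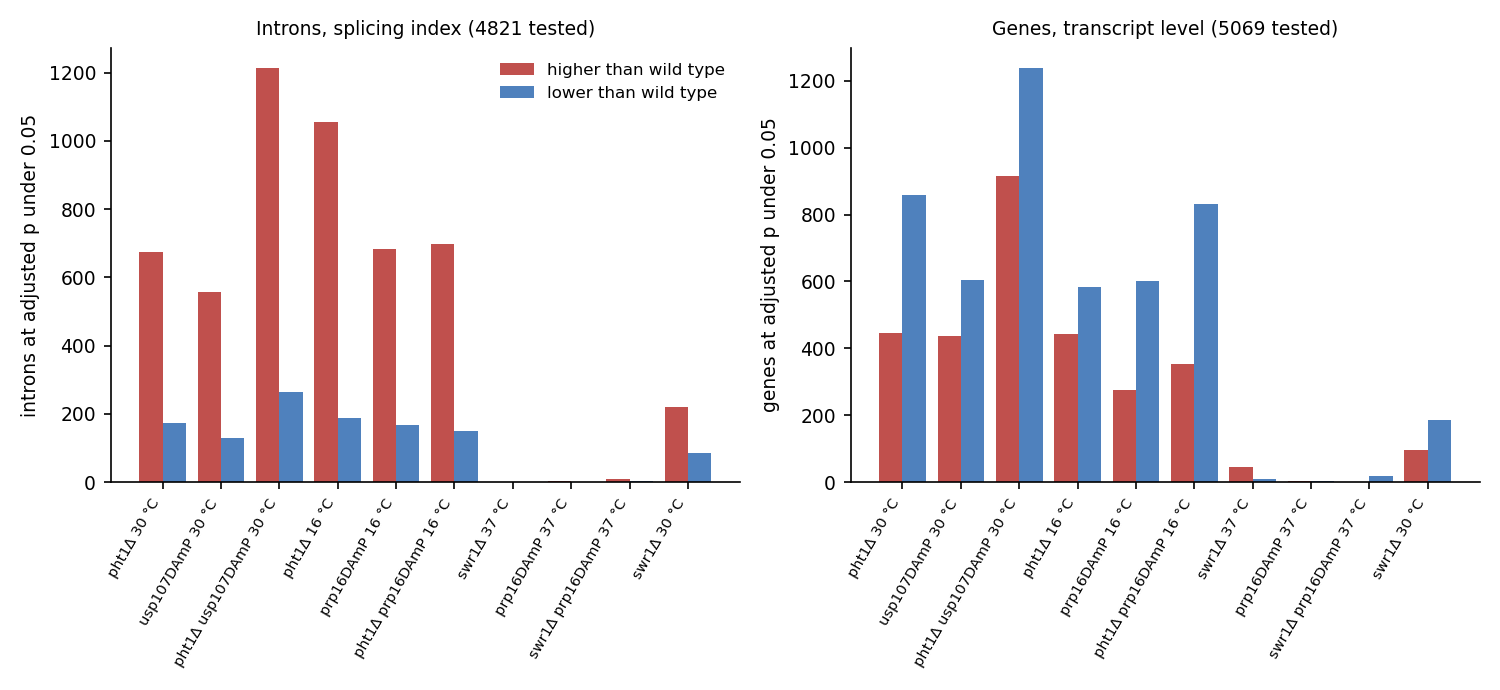
Bars give the number of introns, of 4821, with a called splicing index (left) and of genes, of 5069, with a called transcript level (right) in each group against wild type, higher and lower separately. Higher indices outnumber lower ones in every group with called introns, 673 against 174 in pht1∆ at 30 °C and 1055 against 187 at 16 °C.

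Transcript levels in pht1∆ at 30 °C rose in 447 and fell in 858 of 5069 genes, or in 856 genes in all without replicate 1, 827 with arrays scaled to equal spread and 253 with only the arrays of the group. SPCC1739.08c (3.05 ± 0.22, adjusted p = 2.7e-10), the subtelomeric helicase gene tlh1 (2.93 ± 0.31, 3.9e-07), mug14 (2.78 ± 0.27), tlh2 (2.41 ± 0.32), gal10, for UDP-galactose epimerase (2.36 ± 0.13, 5.3e-12), and the hexose transporter gene ght5 (2.15 ± 0.25) rose most. The largest falls were in mfm2 (−2.87 ± 0.21, 3.5e-10), the mating-type genes mat1-Mc (−2.85 ± 0.17) and mat3-Mc (−2.83 ± 0.18), and nrg1 (−2.42 ± 0.30). The tlh genes, and both Mc copies, share sequence, so their signals cannot be assigned to a copy. Ribosomal protein transcripts fell as a group, 58 of 141 and none higher, or 65 adjusted over the list alone, led by rpl3801 (−1.34), rpl3703 (−1.10) and rps21 (−1.09). Their camera adjusted p was 8.1e-10, and 0.813 with an estimated correlation. The mating list went both ways, with 7 higher and 4 lower of 22 (8 and 4 adjusted over the list alone, median 0.20, mean −0.0050, camera adjusted p = 0.235), as did the subtelomere list with 6 and 4 of 18, also adjusted over the list alone (0.452).

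For arrays labelled swr1∆ at 30 °C, the question was whether introns changed as in pht1∆. Intron 1 of bud20 rose by 3.17 ± 0.25 (adjusted p = 5.4e-10), mfm2 by 2.58 ± 0.25 (exon feature −2.58), SPAC186.08c by 2.53 ± 0.20, ers1 intron 8 by 1.94 ± 0.22 and rpc82 by 1.77 ± 0.15. Intron 1 of hpz1 fell by 1.75 ± 0.15 (0.15 with junction features as the reference), and introns 3 and 1 of bdp1, a TFIIIB subunit, by 1.66 ± 0.27 and 1.01, the second not called without replicate 2. In all, 220 introns were higher and 84 lower, in 262 genes. With junction features as the reference 80 were higher and 110 lower. Among called introns with a flat exon feature 60.8% of 74 were higher (48.8 to 72.0). The count of 304 depended on single arrays, with 43 without replicate 1, 101 without replicate 2 and 565 without replicate 3, and fell to 14 with only the 3 arrays of the group and to 57 without both arrays with the most repeated values.

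Transcripts in swr1∆ at 30 °C rose in 97 and fell in 185 genes. The counts were 53, 72 and 597 in all without replicates 1, 2 and 3, and 2 with only the arrays of the group. Transcripts of hpz1 (1.85 ± 0.19, adjusted p = 5.9e-07), tlh1 (1.44 ± 0.31, arrays at 0.05, 2.33 and 1.94, not called without replicate 2) and pfl8 (1.32 ± 0.18) rose. Those of mat1-Mc (−2.65 ± 0.17, 6.7e-11), mfm2 (−2.58 ± 0.21) and mat3-Mc (−2.56 ± 0.18) fell. Of 141 ribosomal protein transcripts 22 fell and none rose (59 and 1 adjusted over the list alone, camera adjusted p = 1.1e-15, and 0.813 with an estimated correlation).

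Set directly against pht1∆ at 30 °C, swr1∆ differed in the index of 13 introns, 1 higher and 12 lower. The lower ones include introns 2, 1 and 3 of SPAC3G6.05 (−2.34 ± 0.28, −1.57 and −1.43), whose exon feature was higher by 2.12, and the higher intron was intron 2 of dic1 (0.80 ± 0.18). The calls of dic1 and of SPAC3G6.05 intron 3 were lost without at least 1 array. The replicate numbers pair these arrays, and with the pair as a block 2 introns passed, with arrays scaled to equal spread 3 and with only both groups 1. Leaving out pht1∆ replicates 1, 2 and 3 gave 20, 46 and 2 calls, and swr1∆ replicates 1 and 3 gave 22 and 25. In 17 fits without an array of another group the count was 8 to 22. At transcript level 80 genes were higher and 40 lower in swr1∆, and 243 in all with the pair as a block, 65 with equal spread and 5 with only both groups. Without pht1∆ usp107DAmP replicate 3 the count was 189. The largest were cbf12 (2.19 ± 0.29, adjusted p = 5.2e-05), SPAC3G6.05 (2.12 ± 0.22) and pfl8 (1.92 ± 0.26), and lower SPCC1739.08c (−2.53 ± 0.30), mug14 (−2.34 ± 0.39) and gal10 (−1.79 ± 0.19).

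**Figure D2:**
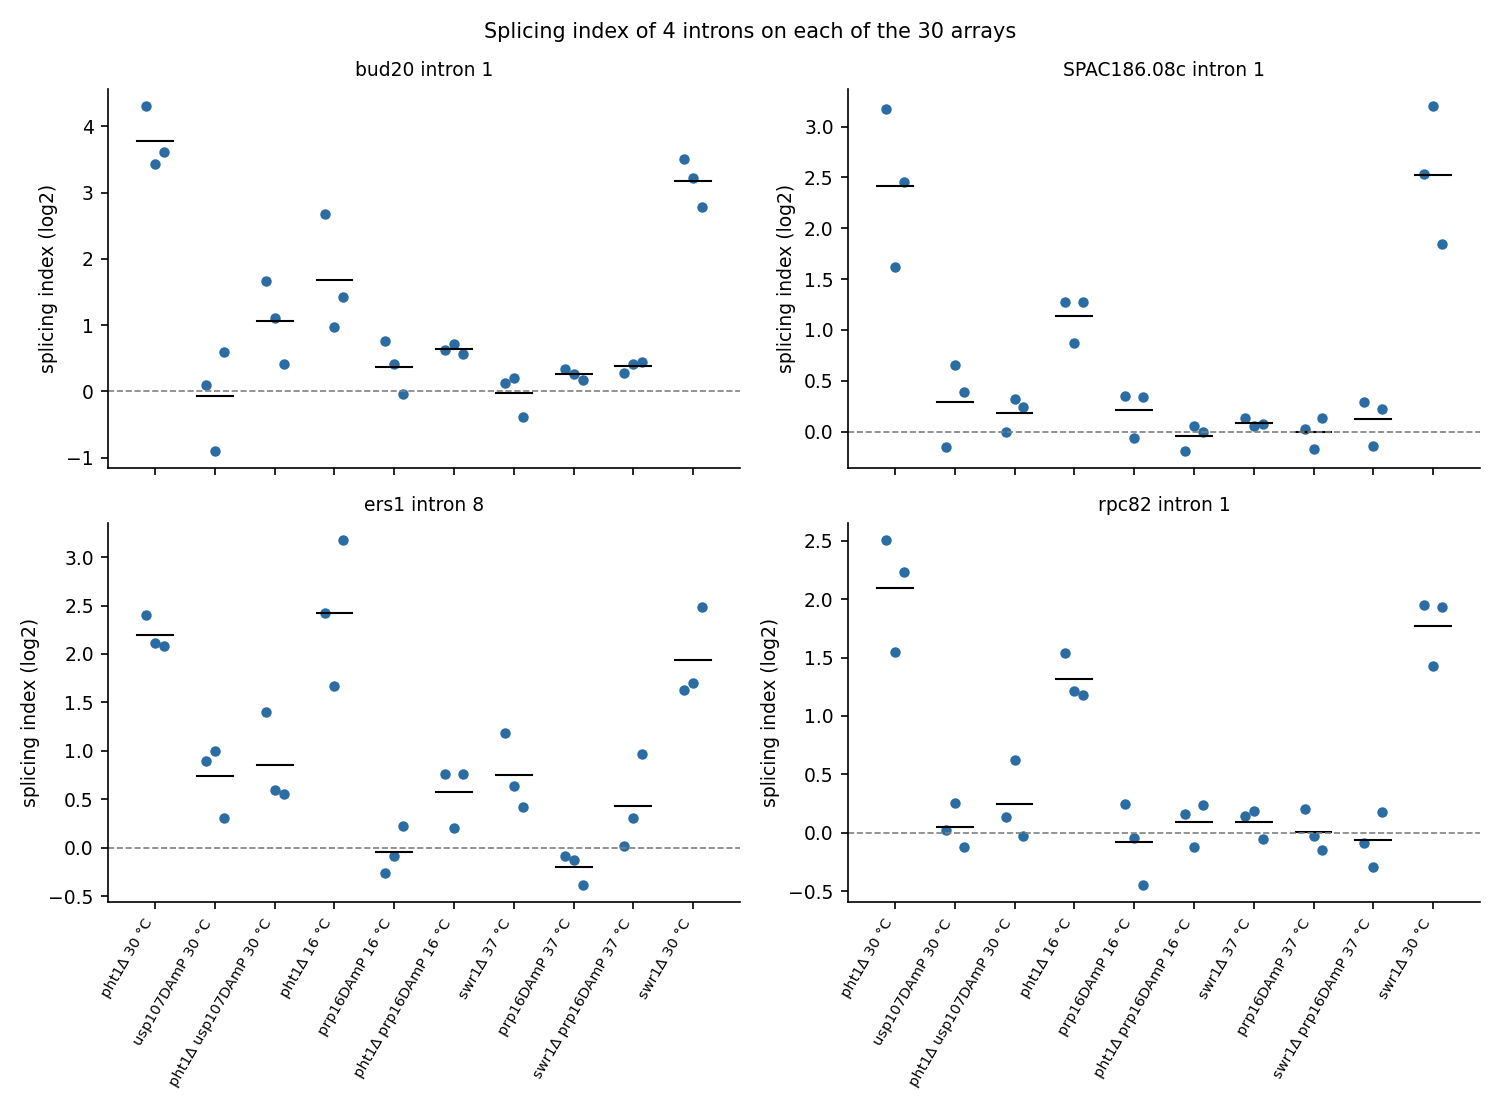
Points give the splicing index (log2) of intron 1 of bud20, intron 1 of SPAC186.08c, intron 8 of ers1 and intron 1 of rpc82 on each of 30 arrays by group, and lines the group means. The means of bud20 are 3.78 in pht1∆ and 3.17 in swr1∆ at 30 °C, and 1.69 in pht1∆ at 16 °C.

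At 16 °C the question was how loss of H2A.Z affects splicing in the cold. In pht1∆, intron 1 of mfm2 had the highest index, 4.69 ± 0.25 (adjusted p = 4.9e-14), with the exon feature at −5.07 and the intron feature at −0.38. Intron 8 of ers1 rose by 2.42 ± 0.22 (6.3e-09), intron 1 of lsd90 by 2.15 ± 0.24 (exon feature 0.18), intron 1 of rec7 by 1.72 ± 0.33 and intron 1 of bud20 by 1.69 ± 0.25. Intron 2 of pop23 fell by 2.09 ± 0.18 (6.3e-09), and intron 1 of sar1, for the COPII GTPase, by 1.23 ± 0.18, each with the intron feature itself lower (−1.61 and −1.14). Intron 1 of hpz1 fell by 1.14 ± 0.15 and was 0.37 with junction features as the reference. In all, 1055 introns were higher and 187 lower, in 938 genes, and 603 were called without replicate 1.

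Of 402 called introns with a flat exon feature in pht1∆ at 16 °C, 94.3% were higher (91.5 to 96.3). In 75.7% of all higher introns the intron feature moved more than the exon feature, with medians of 0.45 and −0.11. Of the lower introns this held for 28.9%, with medians of −0.13 for the intron and 0.29 for the exon feature. Transcripts rose in 443 and fell in 584 genes, and 539 and 615 were called without replicates 1 and 3. The largest rises were cmt2 (3.36 ± 0.37, adjusted p = 5.4e-07), the metallothionein gene zym1 (2.53 ± 0.25), tlh1 (2.41 ± 0.31) and ddr48 (2.11 ± 0.23). Transcripts of mfm2 (−5.07 ± 0.21, 3.3e-15), mat3-Mc (−2.85 ± 0.18), mat1-Mc (−2.79 ± 0.17) and nrg1 (−2.43 ± 0.30) fell most. Among 9 phosphate genes, the acid phosphatase gene pho1 (−1.89 ± 0.22) and the transporter gene pho84 (−1.05) fell and none rose, as adjusted over the list alone, with a median of 0.02 and a mean of −0.26 over the list (camera adjusted p = 0.612).

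Between temperatures, the index in pht1∆ was higher at 16 than at 30 °C for 322 introns and lower for 157, in 411 genes. This compares ratios to wild-type RNA, so any change of the wild-type RNA between the arrays of the temperatures is part of it. The same holds for the comparisons of temperatures in swr1∆ and prp16DAmP below. Intron 1 of mfm2 (1.84 ± 0.36), intron 2 of ste13 (1.55 ± 0.26) and intron 1 of ppm1 (1.46 ± 0.22) were higher at 16 °C, and intron 1 of bud20 (−2.09 ± 0.35, adjusted p = 5.0e-04), intron 1 of alb1 (−1.74 ± 0.49) and intron 2 of SPAC3G6.05 (−1.63) lower. The alb1 call was lost without replicate 1 of either group. In 86.6% of the higher introns the intron feature moved more than the exon feature. Without pht1∆ 30 °C replicate 2 the count was 308, and without pht1∆ 16 °C replicate 1 it was 189. Arrays scaled to equal spread gave 163 and 48, exon and junction features as the reference 714 and 171, and only both groups 124 in all.

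The series title names weak introns, so introns were compared by their splice sites. In pht1∆ at 16 °C the index rose in 24.8% of introns with a weak 5′ splice site (369 of 1490, lowest tertile of scores) and in 19.8% of those with a strong site (242 of 1224), an odds ratio of 1.34 (Fisher's exact test, adjusted p = 0.0151). In genes with a flat exon feature the shares were 22.1% and 16.8% (odds ratio 1.41, adjusted p = 0.0340). On each of the 3 arrays the median index of introns with weak sites was above that of introns with strong sites, by 0.047 ± 0.025 (SD), and by 0.027 ± 0.011 where introns were split at the median score. Long introns stood out more. Of introns of 72 bases or more 27.7% rose, and of those up to 49 bases 16.0% (odds ratio of short against long 0.498, adjusted p = 1.3e-12, and 0.408 with adjusted p = 1.1e-08 in genes with a flat exon feature). A branch site at least 13 bases from the 3′ splice site went with 27.3% risen introns, and a branch site up to 9 bases away with 19.7% (odds ratio 0.653, adjusted p = 3.3e-05). Whether this holds at equal intron length was not tested. Probe sequences were not used, so whether the feature of a short intron lies wholly within it is not known here. Branch site scores did not separate the introns, with 22.9% in the lowest and 22.6% in the highest tertile (odds ratio 1.01, adjusted p = 0.954).

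No other group tested against wild type had a called difference by 5′ splice site. The odds ratios were 1.07 in pht1∆ at 30 °C (14.5% against 13.6%, adjusted p = 0.670), 1.08 in swr1∆ at 30 °C (0.803), 0.889 in prp16DAmP at 16 °C (0.418), 0.805 in pht1∆ prp16DAmP (0.136), 0.868 in pht1∆ usp107DAmP (0.207) and 0.818 in usp107DAmP (0.199), by Fisher's exact test. The median difference between weak and strong sites was 0.05 in pht1∆ at 16 °C and 0.02 at 30 °C (exact permutation p = 0.3). With 3 against 3 arrays this test cannot go below 0.1, so it decides for no pair of groups whether the values differ. Length also parted the introns in usp107DAmP (odds ratio 0.570, adjusted p = 4.1e-05) and pht1∆ prp16DAmP (0.748, adjusted p = 0.0347), and those higher at 16 than at 30 °C in pht1∆ (0.538, adjusted p = 4.3e-04). In usp107DAmP this came mostly from 1 array, since the median index of short introns minus that of long introns was −0.108 on replicate 1, −0.0164 on replicate 2 and 0.00448 on replicate 3, and its mean of −0.0398 became −0.00597 without replicate 1. In pht1∆ prp16DAmP it was −0.0291 for the index but 0.00126 for the intron features alone, so the difference there lay in the exon features.

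**Figure D3:**
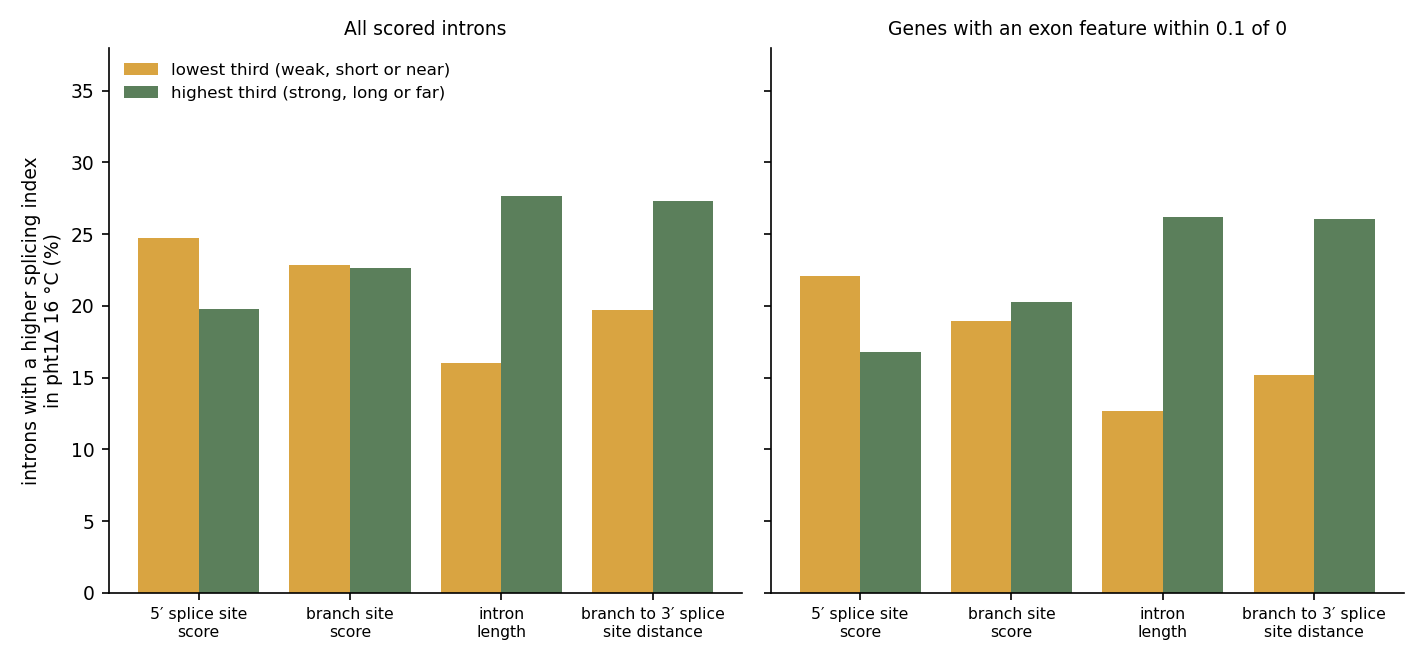
Bars give the percentage of introns with a risen index in pht1∆ at 16 °C in the lowest and the highest tertile of 5′ splice site score, branch site score, length and distance from branch site to 3′ splice site, for all scored introns and for genes with a flat exon feature. The shares are 24.8% and 19.8% for the 5′ splice site score and 16.0% and 27.7% for length.

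For the pairing of H2A.Z with the U1 snRNP, arrays labelled usp107DAmP, whose usp107 feature was −0.01, and pht1∆ usp107DAmP, whose pht1 feature was 0.02, were measured at 30 °C. In usp107DAmP, intron 3 of the arginine methyltransferase gene rmt1 rose by 1.47 ± 0.21 (adjusted p = 1.1e-04), intron 2 of dip1 by 1.27 ± 0.21, and intron 1 of the septin gene spn3 by 1.14 ± 0.28, the last not without replicate 3. Intron 2 of SPAC222.18 fell by 1.29 ± 0.23 and intron 1 of rps2502 by 1.07. Here 557 introns were higher and 129 lower, in 487 genes. The count of 686 was 378 without replicate 1, 155 without replicate 2, and 0 by limma on the 3 arrays of the group alone, against 1371 at unadjusted p under 0.05 in the fit over all arrays. In the double mutant rmt1 intron 3 rose by 1.49 ± 0.21, intron 3 of nrk1 by 1.43 ± 0.11 (1e-09), intron 2 of SPAC3G6.05 by 1.35 ± 0.20 and intron 1 of the fatty acid elongase gene elo2 by 1.32 ± 0.25. SPAC222.18 intron 2 fell by 1.16 ± 0.23, and introns 1, 3, 4 and 2 of vma3, a subunit of the vacuolar ATPase, by 1.09, 1.05, 1.02 and 0.98 with a shared exon feature at 1.14. Here 1212 introns were higher and 264 lower, in 931 genes, or 599 in all without replicate 2, 527 with arrays scaled to equal spread, and 136 with the arrays of the group alone.

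Transcripts in usp107DAmP rose in 437 and fell in 603 genes, and 403 and 293 were called without replicates 1 and 2, and 65 with only the arrays of the group. Of those changed at least 1.5-fold more rose than fell, 122 and 72. The heat shock genes hsp9 (2.51 ± 0.25, adjusted p = 5.5e-07) and hsp104 (1.76 ± 0.22), cmt2 (2.09 ± 0.37) and the peroxiredoxin gene pmp20 (1.71) rose most among genes with the same sign on all 3 arrays, and urg2 (−2.10 ± 0.38) and ftm1 (−1.49), of a family with shared sequence, fell most. Of 24 heat shock genes 14 rose and none fell, or 15 and 1 adjusted over the list alone (camera adjusted p = 5.6e-07, and 0.813 with an estimated correlation), among them hsp16 (2.42 ± 0.52, SD 2.40) and hsp90 (0.88). Of 22 core stress genes 10 rose and 1 fell, or 13 and 1 adjusted over the list alone (camera adjusted p = 2.4e-05, and 0.813 with an estimated correlation), led by gst2 (1.38) and gpd1 (1.26). Transcripts in the double mutant rose in 914 and fell in 1237 genes, and 1111 were called without replicate 2, 1017 with arrays scaled to equal spread and 29 with only the arrays of the group. Transcripts of hsp9 (2.76 ± 0.25), cmt2 (2.52 ± 0.37), tlh1 (2.31 ± 0.31) and tlh2 (1.93 ± 0.32) rose, and pfl8 (−1.58 ± 0.18), thi201 (−1.43 ± 0.18) and the U1 snRNP gene usp109 (−1.29 ± 0.13) fell. The tlh1 level was 0.01 in usp107DAmP.

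Against pht1∆, the arrays labelled pht1∆ usp107DAmP had a higher index in 519 introns and a lower one in 337, in 613 genes. Intron 1 of elo2 (2.00 ± 0.35, adjusted p = 6.2e-04), intron 2 of SPMIT.01 (1.54) and intron 4 of hem12 (1.48 ± 0.21) were higher. The largest negative differences were in intron 1 of mfm2 (−3.01 ± 0.36), bud20 (−2.72 ± 0.35), SPAC186.08c (−2.23 ± 0.28) and rpc82 (−1.85 ± 0.22). The count of 856 was 370 without double mutant replicate 2, 97 with arrays scaled to equal spread and 12 with only the groups compared. With exon and junction features as the reference 769 were higher and 179 lower. Against usp107DAmP, 10 introns were higher and 2 lower, led by introns 3 and 1 of dim1 (1.33 ± 0.22, adjusted p = 0.0072, and 1.25) and intron 1 of qcr10 (1.19), with introns 2 and 1 of tbc1 lower (−0.96 ± 0.17 and −0.73). The exon features of dim1 and tbc1 were −1.17 and 0.93, and each of these calls was lost without at least 1 array. These arrays pair by number, and with the pair as a block 0 introns passed in limma, against 475 at unadjusted p under 0.05 without the block. The 12 calls became 1 without usp107DAmP replicate 1, and 2, 0 and 143 without double mutant replicates 1, 2 and 3. Equal spread and a fit on only both groups each gave 0. In 5 fits without an array from 37 °C the count was 4 to 7.

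The interaction at 30 °C, which asks whether the arrays labelled as the double mutant depart from the sum of the singles, was called for 14 introns, 3 higher and 11 lower. Lower were mfm2 (−2.73 ± 0.44), bud20 (−2.65 ± 0.43, adjusted p = 0.001), SPAC186.08c (−2.53 ± 0.35), ers1 intron 8 (−2.08 ± 0.37) and rpc82 (−1.90 ± 0.27). Higher were hpz1 (1.44 ± 0.26, but −1.07 with junction features as the reference), nta1 intron 1 (1.08) and prf1 intron 1 (0.90), of which nta1 and prf1 were lost without at least 1 array. With the mean of prp16DAmP at 16 and 37 °C added to remove a shared offset, 13 passed, 10 of them among the 14, and prf1 did not. In the 11 lower introns the median index was 1.61 in pht1∆, 0.12 in usp107DAmP and 0.17 in the double mutant. The count was 9 without pht1∆ replicate 1, 8 without usp107DAmP replicate 1, and 23 and 33 without double mutant replicates 1 and 3. In 12 fits without an array of another group it was 9 to 27. Arrays scaled to equal spread gave 0 higher and 3 lower introns, and the groups alone 0 in all by limma, where the fit over all arrays has 480 at unadjusted p under 0.05.

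The second pairing, with Prp16, was measured at 16 °C, on arrays labelled pht1∆ prp16DAmP whose pht1 feature was −0.03. In prp16DAmP, intron 1 of rps2802 rose by 1.48 ± 0.26 (adjusted p = 4.5e-04), introns 3 and 1 of the glutaredoxin gene grx1 by 1.23 ± 0.27 and 1.19, and intron 1 of ubc13 by 1.17 ± 0.23. Intron 3 of srb11 fell by 0.94 ± 0.21 and intron 2 of SPBC16A3.12c by 0.92. In all 682 introns were higher and 168 lower, in 598 genes. Without replicate 1 the count was 114, and rps2802, grx1 and srb11 were not called. Without replicate 2 it was 547, with exon and junction features as the reference 540, and with the arrays of the group alone 411. In pht1∆ prp16DAmP, rmt1 intron 3 rose by 1.69 ± 0.21 (1e-05), rpl2501 intron 1 by 1.47 ± 0.22, ell1 intron 2 by 1.46 ± 0.26 and intron 3 of the retromer gene vps35 by 1.44 ± 0.17. Intron 2 of brf1 fell by 1.01 ± 0.31, a call lost without any of the 3 arrays, and intron 1 of wbp4 by 0.98 ± 0.16. In all 698 introns were higher and 149 lower, in 582 genes, or 192 and 396 in all without replicates 1 and 2, and 458 with exon and junction and 515 with junction features as the reference.

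Transcripts in prp16DAmP at 16 °C rose in 275 and fell in 601 genes, 186 and 500 in all without replicates 1 and 2. The mitochondrial SPMIT.11 (−1.67 ± 0.21) and SPMIT.10 (−1.40 ± 0.17) fell most, and dcp1 (0.81 ± 0.20, not called without replicate 1) rose most. In pht1∆ prp16DAmP 354 rose and 833 fell, 309 and 598 in all without replicates 1 and 2. There cmt2 rose by 1.18 ± 0.37 and nrg1 fell by 2.02 ± 0.30 (adjusted p = 7e-05), the cmt2 call being lost without replicate 2 or 3. Ribosomal protein transcripts fell in both, 81 of 141 with 1 higher in prp16DAmP (90 and 2 adjusted over the list alone, camera adjusted p = 4.5e-14, and 0.813 with an estimated correlation) and 76 with 3 higher in the double mutant (86 and 3, camera adjusted p = 4.9e-09, and 0.813 with an estimated correlation). The index of ribosomal protein introns rose with it, 37 of 91 with 1 lower in prp16DAmP (43 and 4 adjusted over the list alone, camera adjusted p = 4.6e-04, and 0.813 with an estimated correlation) and 31 with 3 lower in the double mutant (37 and 3, camera adjusted p = 7.8e-04, and 0.813 with an estimated correlation). Among the called introns with a flat exon feature 75.4% of 69 were higher in prp16DAmP and 85.9% of 64 in the double mutant.

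Against pht1∆ at 16 °C, the arrays labelled pht1∆ prp16DAmP had a higher index in 234 introns and a lower one in 400, in 496 genes. Intron 2 of pop23 (2.27 ± 0.26, adjusted p = 2.9e-06), intron 1 of sar1 (1.70 ± 0.26) and intron 2 of ell1 (1.49) were higher, the ell1 call not without double mutant replicate 2. Intron 1 of mfm2 (−4.42 ± 0.36), intron 8 of ers1 (−1.85 ± 0.30), intron 1 of rpl2302 (−1.84 ± 0.34) and intron 2 of ste13 (−1.61 ± 0.26) were lower. Higher introns were rarer among weak 5′ splice sites, 3.49% against 6.45% (odds ratio 0.524, Fisher's exact test, adjusted p = 0.00381). The count of 634 was 294 without pht1∆ replicate 1, and 255 and 415 without double mutant replicates 1 and 2. With exon and junction features as the reference 159 were higher and 507 lower. Against prp16DAmP, introns 2 and 1 of the GTPase gene rhb1 were lower (−0.94 ± 0.17, adjusted p = 0.015, and −0.91 ± 0.15), with a shared exon feature at 0.89, and intron 1 was 0.28 with junction features as the reference. These arrays pair by number, and with the pair as a block 0 introns passed in limma, against 347 at unadjusted p under 0.05 without the block. The 2 calls became 1, 14 and 4 without prp16DAmP replicates 1, 2 and 3, and 0 without double mutant replicate 2.

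The interaction at 16 °C was called for 110 introns, 7 higher and 103 lower, in 105 genes. Higher were pop23 intron 2 (1.88 ± 0.32, adjusted p = 0.002), tbc13 intron 2 (1.58) and sar1 intron 1 (1.29), tbc13 and sar1 not without at least 1 array, and lower mfm2 (−4.69 ± 0.44), ers1 intron 8 (−1.81 ± 0.37), wtf14 intron 1 (−1.69 ± 0.24) and ste13 intron 2 (−1.59 ± 0.32). The wtf genes are a family with shared sequence, so that value is uncertain. In the 103 lower introns the median index was 0.81 in pht1∆, 0.20 in prp16DAmP, 0.09 in the double mutant and 0.10 in the other groups. With the mean of usp107DAmP and of prp16DAmP at 37 °C added to remove a shared offset, 31 passed, 9 higher and 22 lower, 24 of them among the 110, and ers1 (−1.54) and tbc13 did not. The count was 38, 204 and 69 without pht1∆ replicates 1, 2 and 3, 39 and 71 without prp16DAmP replicates 1 and 3, and 35 and 62 without double mutant replicates 1 and 2. Arrays scaled to equal spread gave 38, exon and junction features as the reference 329, and junction features 248.

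At 37 °C swr1∆, and not pht1∆, was combined with prp16DAmP, and how many values passed depended on how the arrays' small spread was treated. With arrays scaled to equal spread the index was called in 532 introns in swr1∆, 560 in prp16DAmP and 189 in the double mutant, and with only the arrays of the group in 325, 283 and 0. In the fit over all arrays without scaling the counts were 0, 3 and 10. In swr1∆ limma called 0 introns, against 459 at unadjusted p under 0.05. Its calls became 7 without replicate 1, 2 without swr1∆ prp16DAmP replicate 3, and 1 and 6 without pht1∆ usp107DAmP replicates 1 and 3. In prp16DAmP, intron 3 of sec59 (1.05 ± 0.17, adjusted p = 0.0022) and intron 1 of rsc1 (0.80 ± 0.12) rose, and intron 1 of SPAC1F12.06c fell by 1.5 ± 0.25 while its exon feature rose to 1.45. Each of these 3 calls was lost without 1 of the group's own arrays, and the count was 1 without replicate 3 and 5 without double mutant replicate 3. In swr1∆ prp16DAmP 8 introns were higher and 2 lower, among them intron 1 of SPCC1672.09 (0.73 ± 0.16), intron 2 of the U1 snRNP gene prp39 (0.67) and intron 3 of ckn1 (0.66 ± 0.11), and lower intron 4 of mug137 (−0.81 ± 0.15). That count was 0 without replicate 1 or 2, 62 without replicate 3, and 5 to 30 in 16 fits without an array of another group.

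Transcripts at 37 °C rose in 45 and fell in 8 genes in swr1∆. The glutathione transferase gene gst2 (1.43 ± 0.33), the polyubiquitin gene ubi4 (1.38 ± 0.18, adjusted p = 1.1e-04), SPAC750.01 (1.26) and ubi2 (1.24 ± 0.15) rose most, and cwf11 (−0.60 ± 0.10), SPAPB1A10.13 (−0.60) and pmp1 (−0.57 ± 0.08) fell most. The calls of gst2, SPAC750.01 and cwf11 were lost without at least 1 array. The count of 53 was 6 and 17 without replicates 2 and 3, and 33 to 35 in 8 fits without an array of another group. Scaled to equal spread, 399 genes rose and 312 fell, and with only the arrays of the group 101 were called. Of 24 heat shock genes 2 rose, wos2 (0.67) and sti1 (0.52), and 9 rose adjusted over the list alone, with none lower (camera adjusted p = 2.3e-04, and 0.813 with an estimated correlation). In prp16DAmP 2 genes rose and 4 fell, SPAC1F12.06c (1.45 ± 0.20) and och1 (0.61) against SPAPB1A10.13 (−0.60), rcl1 (−0.59), swd1 (−0.58) and pmp1 (−0.43), all lost without replicate 1. That count was 0 and 2 without replicates 1 and 2, and 11 without swr1∆ prp16DAmP replicate 3, but 612 with equal spread and 724 with only the arrays of the group. In swr1∆ prp16DAmP 1 rose and 17 fell, sid4 (0.42 ± 0.09) against SPAPB24D3.07c (−1.39 ± 0.23), SPMIT.11 (−1.09 ± 0.21) and others, all lost without replicate 1 or 2. The count was 132 with equal spread, 0 with only the arrays of the group, 1, 0 and 123 without replicates 1, 2 and 3, and 9 to 58 in 14 fits without an array of another group.

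Between groups at 37 °C, swr1∆ prp16DAmP had a higher index than swr1∆ in 30 introns and a lower one in 10. Intron 1 of dpc13 (1.31 ± 0.21, adjusted p = 0.0027), intron 1 of ppx1 (1.16, but −0.10 with junction features as the reference) and intron 2 of ysh1 (1.08) were higher, and intron 4 of mug137 lower (−1.45 ± 0.21, 5.4e-04). All of these but mug137 were lost without at least 1 array. The 40 calls became 82, 7 and 1 without swr1∆ replicates 1, 2 and 3, and 4, 2 and 218 without double mutant replicates 1, 2 and 3. Without pht1∆ usp107DAmP replicate 3 there were 71. Some swr1∆ arrays ran against the double mutant (r down to −0.53), and with the sign of the swr1∆ arrays turned 1 intron passed. Scaled to equal spread, 299 were higher and 236 lower, and exon and junction features as the reference gave 3 in all and junction features 13. Against prp16DAmP limma called 0 introns (118 at unadjusted p under 0.05, fewer than arise where nothing differs). There was 1 call without usp107DAmP replicate 2 or 3, and 3 without double mutant replicate 3. The interaction was called for 0 introns (376 at unadjusted p under 0.05), with 4 without swr1∆ replicate 1, 1 without prp16DAmP replicate 3, 59 without double mutant replicate 3, 78 with the mean of usp107DAmP and of prp16DAmP at 16 °C added, and 216 with equal spread.

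Across temperatures, swr1∆ at 37 °C had a higher index than at 30 °C in 5 introns and a lower one in 11. Intron 1 of hpz1 (1.04 ± 0.21) and of rli1 (0.92) were higher, and bud20 (−3.19 ± 0.35, adjusted p = 2.1e-06), mfm2 (−2.69 ± 0.36) and SPAC186.08c (−2.44 ± 0.28) lower. The calls of hpz1 and rli1 were lost without at least 1 array. The 16 calls became 8 and 7 without 37 °C replicates 2 and 3, 10 and 204 without 30 °C replicates 1 and 3, and 25 to 43 in 7 fits without an array of another group. Scaled to equal spread, 82 were higher and 116 lower, and with junction features as the reference 22 and 7. A fit on only both groups gave 7 in all. With the 37 °C sign turned the count was far higher, as given below. The mean of mat1-Mc, mat3-Mc and mfm2 was −2.60 in swr1∆ at 30 °C and −0.06 at 37 °C. A difference of strain between these sets can therefore not be told apart from temperature. In prp16DAmP 15 introns were higher at 37 than at 16 °C and 47 lower, in 52 genes. Introns 4, 2 and 3 of SPAC11E3.10 (1.30, 1.29 and 1.15, exon feature −1.16) were higher, intron 3 at −0.26 with junction features as the reference. Intron 1 of SPAC1F12.06c (−1.96 ± 0.36) and introns 1 and 3 of grx1 (−1.57 ± 0.38 and −1.53, exon feature 1.57) were lower. The 62 calls became 4 and 40 without 16 °C replicates 1 and 2, and 3, 14 and 5 without 37 °C replicates 1, 2 and 3, and all of these named calls were lost without at least 1 array. Scaled to equal spread, 65 were higher and 106 lower. A fit on only both groups gave 170 in all, exon and junction features as the reference 25 and junction features 10.

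**Figure D4:**
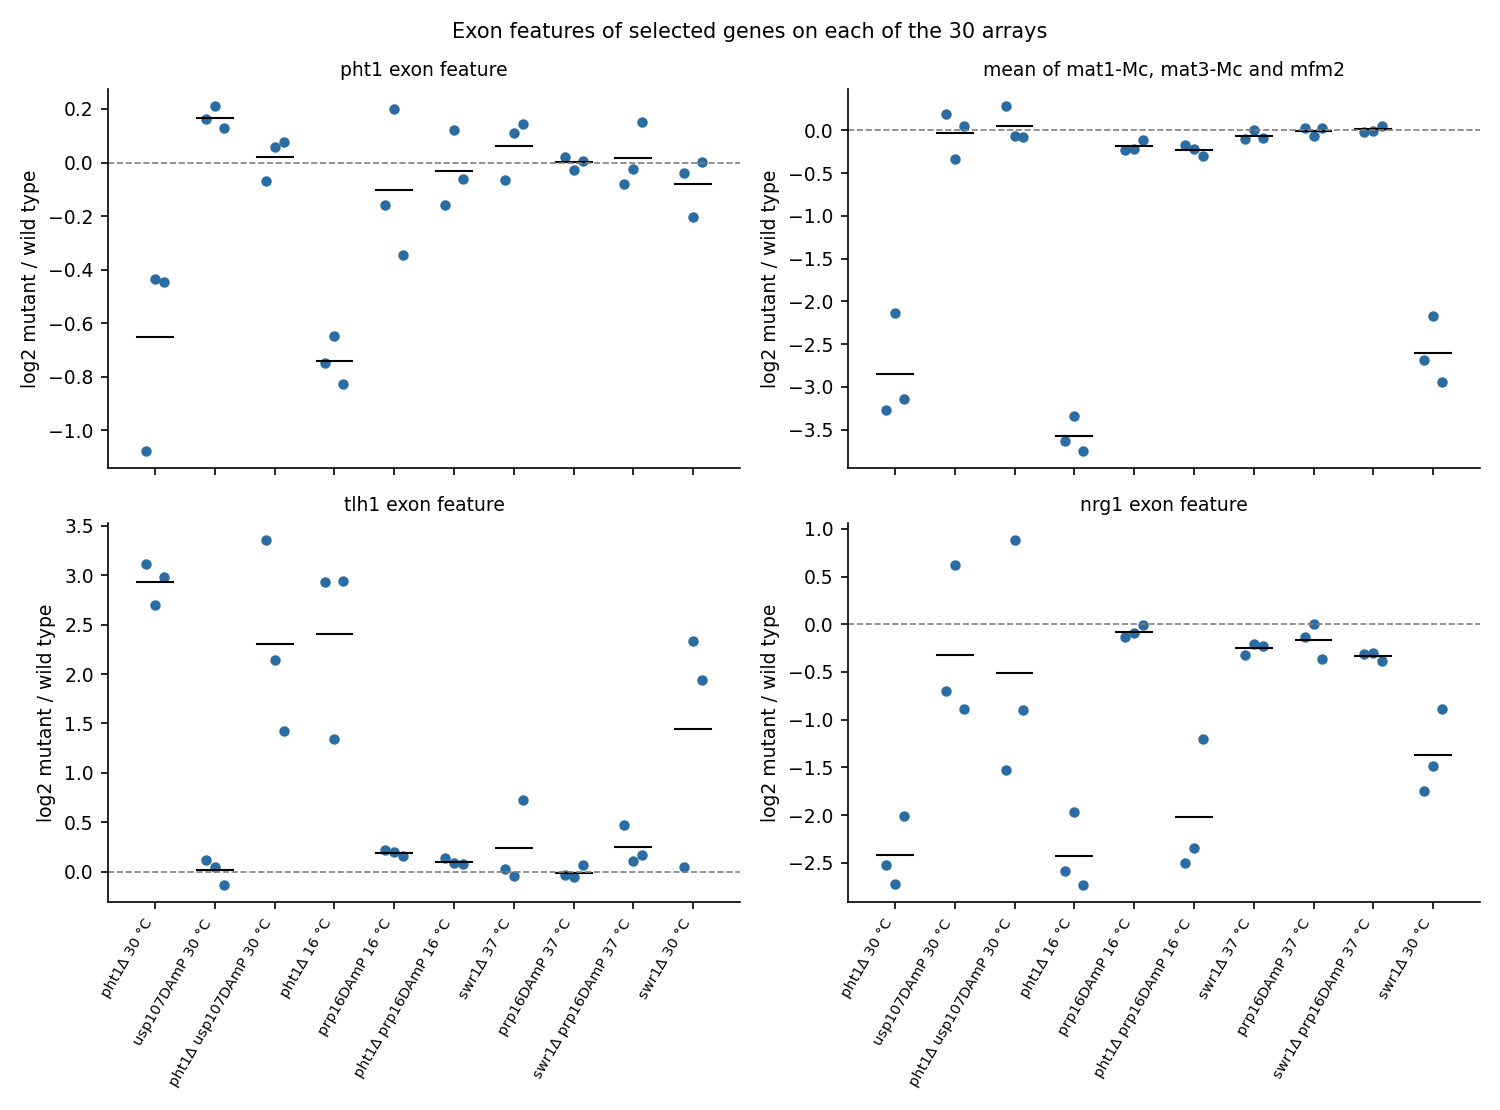
Points give transcript levels (log2 of mutant over wild type) on each of 30 arrays by group for pht1, the mean of mat1-Mc, mat3-Mc and mfm2, tlh1 and nrg1, and lines the group means. The mean of the mating-type genes is −2.85 in pht1∆ and −2.60 in swr1∆ at 30 °C and −3.57 in pht1∆ at 16 °C.

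Further list calls were 4 heat shock genes higher and none lower in pht1∆ at 16 °C, or 2 adjusted over the list alone (camera adjusted p = 0.0451, and 0.860 with an estimated correlation), led by hsp3101 (1.12), and 2 ribosomal protein transcripts lower in swr1∆ prp16DAmP at 37 °C, or 7 adjusted over the list alone (2.8e-06, and 0.856 with an estimated correlation). The index of ribosomal protein introns was higher in pht1∆ usp107DAmP than in usp107DAmP as a list (median 0.26, camera adjusted p = 1.4e-04, and 0.813 with an estimated correlation), with 0 introns called by limma and 1 adjusted over the list alone. It was lower in prp16DAmP at 37 than at 16 °C, with 7 lower introns, or 17 and 1 higher adjusted over the list alone (median −0.26, 5.0e-04, and 0.813 with an estimated correlation). The index depends on the exon feature by construction, and whether these list results rest on exon features was not tested.

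None of the other lists was called by camera against wild type. Of 15 SWR complex genes 5 rose and 3 fell in pht1∆ at 16 °C, or 6 and 3 adjusted over the list alone (camera adjusted p = 0.203). Of 11 histone genes 6 fell and none rose in pht1∆ prp16DAmP, as adjusted over the list alone, led by hht1 (−0.97) and hhf2 (−0.84), with a camera adjusted p of 0.0677 and 0.826 with an estimated correlation, and 6 rose and 1 fell in pht1∆ usp107DAmP. Of 144 meiosis genes 37 rose and 21 fell in pht1∆ usp107DAmP, 36 and 21 adjusted over the list alone (0.098). Of 51 chromosome segregation genes 1 rose and 8 fell in pht1∆ at 30 °C, 0 and 8 adjusted over the list alone, the kinetochore genes cnp3 (−1.05) and spc7 (−0.64) among them. In pht1∆ at 16 °C 12 of 60 introns of that list had a higher and 2 a lower index (camera adjusted p = 0.662, fry adjusted p = 7.0e-04), led by intron 1 of mis16 (0.87 ± 0.12). Of 23 tubulin and microtubule genes 7 rose and 7 fell in pht1∆ usp107DAmP (0.946), and 6 of their 34 introns had a higher index in pht1∆ at 16 °C, led by alp6 intron 3 (0.88 ± 0.15). Of 118 introns of spliceosome genes 38 were higher and 1 lower in pht1∆ usp107DAmP, or 39 and 2 adjusted over the list alone (camera adjusted p = 0.235, fry adjusted p = 5.6e-05), led by prp39 intron 6 (1.11) and srp2 intron 6 (1.06). In pht1∆ at 16 °C 2 mating genes rose and 6 fell of 22, or 2 and 7 adjusted over the list alone, with a median of 0.02 and a mean of −0.36 (camera adjusted p = 0.300), and the subtelomere list had a median of −0.01 and a mean of 0.19. Over all lists and comparisons 13 of 362 camera tests passed, 0 with an estimated correlation and 34 with fry, in a count that was 20 without pht1∆ 30 °C replicate 1, 30 and 20 without swr1∆ 37 °C replicates 1 and 3, and 24 without swr1∆ 30 °C replicate 1.

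The median index over all introns was above 0 on all 30 arrays. It was 0.07 ± 0.05 (SD, n = 3) in pht1∆ at 30 °C, 0.11 ± 0.01 at 16 °C, 0.08 ± 0.02 in usp107DAmP and 0.13 ± 0.05 in its double mutant, 0.11 ± 0.04 in prp16DAmP at 16 °C and 0.10 ± 0.02 in its double mutant, 0.06 ± 0.04 in swr1∆ at 30 °C and 0.03 ± 0.02 at 37 °C, 0.03 ± 0.02 in prp16DAmP at 37 °C and 0.05 ± 0.03 in its double mutant. The exact permutation tests between groups reached their lowest possible value of 0.1 for prp16DAmP at 37 against 16 °C (a difference of −0.08), and 3 against 3 arrays cannot pass.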

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

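The tests of the arrays labelled as double mutants, of the mating-type genes, and of a dye or wild-type offset were chosen only after the result was seen, as were the removal of a shared offset from the interactions and the splits that keep the replicate numbers. The other splits of the arrays and the share of higher among called introns with a flat exon feature were written down before their results were seen, but not the tests of splice sites on such genes.

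The results taken up here are effects that differ between backgrounds or temperatures by a test of the difference itself. The interaction of pht1∆ with usp107DAmP at 30 °C was called for 14 introns and that of pht1∆ with prp16DAmP at 16 °C for 110. Between temperatures, 479 introns differed in pht1∆, 16 in swr1∆ and 62 in prp16DAmP. Of 100 splits of the 9 arrays at 30 °C, 62 gave at least 14 calls, the highest other 976, and of 100 splits at 16 °C, 15 gave at least 110, the highest other 1322. For the interaction at 37 °C all 100 splits reached the real count of 0, the highest other being 40. A count of 0 is reached by any split, so this decides nothing at 37 °C. Of all 108 splits that keep 1 array of each replicate number in every group, 63 reached the real count at 30 °C (highest other 1605) and 22 at 16 °C (1320). So chance is not excluded for the interactions at 30 and 16 °C. Splits with several times the real count point to a structure of the samples, which here includes the groups that are mixed and the shared offset that an interaction keeps. With that offset taken from the groups without a deletion, 13 introns were called at 30 °C, 10 of them among the 14, and 31 at 16 °C, 24 of them among the 110.

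For the other comparisons 10 splits of the 6 arrays exist, too few for a share under 0.05. The real split gave 479 calls between temperatures in pht1∆ (highest other 3), 16 in swr1∆ (2) and 62 in prp16DAmP (1). For the double mutants it gave 856 against pht1∆ at 30 °C (215), 634 against pht1∆ at 16 °C (0) and 40 against swr1∆ at 37 °C (5), and in these 6 comparisons 1 of 10 splits, the real one, was as large. Against prp16DAmP at 37 °C all 10 splits gave 0. Where the replicate numbers pair the arrays, splits that part all pairs are the ones to compare. Against usp107DAmP the real 12 calls stood beside at most 0 among those splits, while 5 of all 10 were as large with up to 436. Against prp16DAmP at 16 °C it was 2 beside 0, with 3 of 10 as large and up to 9. For swr1∆ against pht1∆ at 30 °C it was 13 beside 2, with 5 of 10 as large and up to 90, and 120 transcripts beside 0, with 3 of 10 as large and up to 186. In these 4 comparisons the splits that call more keep a pair of the same number on 1 side, which points to a structure that the numbers carry.

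The pht1 feature was low in the pht1∆ arrays and near 0 in those labelled pht1∆ usp107DAmP and pht1∆ prp16DAmP, and if the latter held no pht1∆ RNA, genes changed in the single mutant would not follow in the double mutant minus the other single. Of 316 genes changed at least 1.5-fold in pht1∆ at 30 °C, outside the mating list, 79.7% kept their sign (95% exact binomial interval 74.9 to 84.0), and of 238 genes at 16 °C 69.7% (63.5 to 75.5). The intervals take genes as independent, which genes measured on the same arrays are not, so they may be too narrow. In 10 differences between groups labelled without pht1∆ (swr1∆ at 30 °C left out) the first set of genes kept at most 58.5% of its signs, but the second up to 73.1%, between usp107DAmP and swr1∆ prp16DAmP. So the tables argue against a plain mislabelling of all arrays of pht1∆ usp107DAmP, where tlh1 also rose to 2.31, but paired by number replicates 1, 2 and 3 kept 80.4, 76.9 and 62.0%, the changes had a median of only 0.27 of those in pht1∆, nrg1 was −1.53, 0.88 and −0.90 on the arrays, and rpc82 intron 1 and SPAC186.08c intron 1 were not called in either double mutant. For pht1∆ prp16DAmP mislabelling cannot be told apart from the label, since tlh1 was 0.10 against 2.41 in pht1∆ and 2 introns and 8 transcripts differed from prp16DAmP, while nrg1 fell by 2.02, and another allele, a feature outside the deletion or a mixed culture were not tested in either.

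The M mating-type genes mat1-Mc, mat3-Mc and mfm2 were low in pht1∆ at 30 °C (mean −2.85 ± 0.62 SD), pht1∆ at 16 °C (−3.57 ± 0.21) and swr1∆ at 30 °C (−2.60 ± 0.40). In the 4 other sets labelled with a deletion the means were 0.05 ± 0.21, −0.23 ± 0.06, −0.06 ± 0.06 and 0.01 ± 0.04, in pht1∆ usp107DAmP, pht1∆ prp16DAmP, swr1∆ at 37 °C and swr1∆ prp16DAmP. The lowest of these, −0.227, does not exclude loss of Pht1 or Swr1 itself, since it stays open whether the swr1∆ sets and pht1∆ prp16DAmP carry the deletion (no fall of swr1 was called, and nrg1 goes with the label but tlh1 against it), pht1∆ usp107DAmP may be a mixed culture as above, and a dependence on the second mutation or on temperature was not tested. A candidate explanation is that the 3 strain sets had another mating type than the wild type they were hybridised with, and map3, a gene of P cells, lay above 0 on 9 of 9 of these arrays while mam2, a gene of M cells, lay below 0 on 9 of 9. On that reading the index of mfm2 intron 1, which rests on its exon feature, may be a matter of the strain and not of splicing. Other leading introns parted the same sets. On the arrays of the 3 sets, SPAC186.08c intron 1 lay at 0.87 to 3.20 and rpc82 intron 1 at 1.18 to 2.50. For bud20 intron 1 it was 0.97 to 4.30. In the 4 other sets these introns lay at −0.19 to 0.32, −0.29 to 0.63 and −0.38 to 1.67. A difference of strain can therefore not be told apart from the deletions for these introns, nor in the comparisons that they lead.

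Introns with a higher index outnumbered those with a lower one in every group with called introns, but not in swr1∆ at 30 °C with junction features as the reference (80 against 110). If intron features near background merely failed to follow falling transcripts, called introns of genes with a flat exon feature would split evenly. In pht1∆ at 16 °C 94.3% of them were higher, which argues against this as the whole cause, and in pht1∆ at 30 °C 70.8%, whose lower bound of 60.7 is only just past the bound of 60 set for the test. In swr1∆ at 30 °C the value of 60.8% leaves it open, and in usp107DAmP, pht1∆ usp107DAmP, pht1∆ prp16DAmP and prp16DAmP at 16 °C, for which no bound was set, it was 89.0% (79.5 to 95.1), 85.5% (77.5 to 91.5), 85.9% (75.0 to 93.4) and 75.4% (63.5 to 84.9). A dye bias or a property of the wild-type RNA stays open too, since the median index was above 0 on 30 of 30 arrays and no dye swap is in the labels, so the excess of higher introns may hold a part that has nothing to do with the mutations.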

How the results depend on the processing

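Leaving out both arrays with the most repeated values, leaving out introns with repeated values, a block within the pair, the removal of a shared offset from interactions, and a turned sign of the swr1∆ arrays at 37 °C were chosen only after the data were seen. Every count here is of introns with a called index unless transcripts are named, and where no construction is given the cause was not tested. Centring each array on its median moved no count by over 1.5 times, and it cancels in the index. No filter on missing values and no other summary of probes could be tried, since no value is missing and each feature has 1 value. Signal over background is not part of the values, so a floor for intron features could not be set, and 1846 introns had no repeated value on any array.

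Scaling arrays to equal spread gave weight to the arrays at 37 °C, whose spread was smallest. There it raised the counts from 0 to 532 in swr1∆, from 3 to 560 in prp16DAmP and from 10 to 189 in the double mutant. Differences at 37 °C rose to 535 (double against swr1∆), 4 (double against prp16DAmP) and 216 (interaction), swr1∆ at 37 against 30 °C to 198 and prp16DAmP at 37 against 16 °C to 171. Counts fell to 386 in pht1∆ at 30 °C, 527 in pht1∆ usp107DAmP, 97 for it against pht1∆, 0 against usp107DAmP, 3 for the interaction at 30 °C and 38 for that at 16 °C. They fell to 3 for swr1∆ against pht1∆ and 211 for pht1∆ at 16 against 30 °C. The 2 lower calls of pht1∆ prp16DAmP against prp16DAmP became 2 lower and 1 higher. Transcript counts became 827 in pht1∆ at 30 °C, 1017 in pht1∆ usp107DAmP, 711 in swr1∆ at 37 °C, 612 in prp16DAmP at 37 °C, 132 in their double mutant and 65 for swr1∆ against pht1∆.

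Fits on only the arrays of the groups compared have fewer arrays behind the spread. The index was then called in 286 introns in pht1∆ at 30 °C, 0 in usp107DAmP, 136 in their double mutant, 411 in prp16DAmP at 16 °C and 14 in swr1∆ at 30 °C. At 37 °C it was called in 325 in swr1∆, 283 in prp16DAmP and 0 in the double mutant. For differences the counts were 12 (pht1∆ usp107DAmP against pht1∆), 0 (against usp107DAmP), 0 (interaction at 30 °C), 0 (pht1∆ prp16DAmP against prp16DAmP) and 1 (swr1∆ against pht1∆). Between temperatures they were 124 in pht1∆, 7 in swr1∆ and 170 in prp16DAmP. Transcripts were called in 253 genes in pht1∆ at 30 °C, 65 in usp107DAmP, 29 in their double mutant and 2 in swr1∆ at 30 °C. At 37 °C they were 101 in swr1∆, 724 in prp16DAmP and 0 in the double mutant, and 5 differed between swr1∆ and pht1∆. Counts of 0 here are from limma, and counts at unadjusted p under 0.05 of the fit over all arrays stand in the results above.

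A change of at least 1.5-fold leaves fewer calls by construction. It left 348 introns in pht1∆ at 30 °C, 215 in usp107DAmP, 570 in their double mutant, 514 in pht1∆ at 16 °C, 252 in prp16DAmP at 16 °C, 298 in their double mutant and 144 in swr1∆ at 30 °C. Transcripts became 324 in pht1∆ at 30 °C (73 higher, 251 lower), 194 in usp107DAmP (122 and 72), 449 in their double mutant, 249 in pht1∆ at 16 °C and 136 in prp16DAmP at 16 °C (13 and 123). They became 199 in pht1∆ prp16DAmP (21 and 178), 29 in swr1∆ and 6 in the double mutant at 37 °C, and 74 in swr1∆ at 30 °C.

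Leaving out introns with repeated values tests fewer introns. It gave 413 in pht1∆ at 30 °C, 392 in usp107DAmP, 683 in their double mutant, 618 in pht1∆ at 16 °C, 348 in prp16DAmP at 16 °C and 377 in their double mutant. At 37 °C it gave 8 in swr1∆ and 6 in the double mutant. Differences gave 385 (pht1∆ usp107DAmP against pht1∆), 0 (against usp107DAmP), 336 (pht1∆ prp16DAmP against pht1∆), 0 (against prp16DAmP) and 3 (swr1∆ against pht1∆), and between temperatures 269 in pht1∆, 30 in swr1∆ and 33 in prp16DAmP. Without both arrays with the most repeated values, swr1∆ at 30 °C had 57 introns and 89 transcripts, swr1∆ between temperatures 10 introns, and 71 transcripts differed between swr1∆ and pht1∆.

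With exon and junction features as the reference the counts were 540 in prp16DAmP at 16 °C, 458 in its double mutant, 1 in prp16DAmP at 37 °C and 0 in its double mutant. Differences were 20 (pht1∆ usp107DAmP against usp107DAmP), 0 (pht1∆ prp16DAmP against prp16DAmP), 329 (interaction at 16 °C) and 3 (double against swr1∆ at 37 °C), and between temperatures 885 in pht1∆ and 25 in prp16DAmP. The split of higher and lower calls became 606 and 285 in pht1∆ at 30 °C and 162 and 99 in swr1∆ at 30 °C. With junction features as the reference, in 4610 introns, the counts were 515 in pht1∆ prp16DAmP at 16 °C, 190 in swr1∆ at 30 °C (80 higher, 110 lower), 3 in swr1∆ and 1 in prp16DAmP at 37 °C, and 6 in their double mutant. Differences were 7 (pht1∆ usp107DAmP against usp107DAmP), 1 (pht1∆ prp16DAmP against prp16DAmP), 248 (interaction at 16 °C), 13 (double against swr1∆ at 37 °C) and 3 (swr1∆ against pht1∆), and between temperatures 29 in swr1∆ and 10 in prp16DAmP. The split became 390 and 238 in pht1∆ at 30 °C, 745 and 151 for pht1∆ usp107DAmP against pht1∆, and 135 and 517 for pht1∆ prp16DAmP against pht1∆. This reference also turned the direction of 12 named introns, the only reversals among named items. Intron 1 of hpz1 became 0.75 in pht1∆ at 30 °C, 0.37 at 16 °C, 0.15 in swr1∆ at 30 °C and −1.07 in the interaction at 30 °C. Intron 1 of csn5 became −0.18 in pht1∆ usp107DAmP, and intron 2 of spo5 0.12 in prp16DAmP and 0.063 in pht1∆ prp16DAmP at 16 °C. Intron 1 of dcp1 became 0.21 in prp16DAmP, of usp108 0.035 in pht1∆ prp16DAmP, and of rhb1 0.28 in pht1∆ prp16DAmP against prp16DAmP. Intron 1 of ppx1 became −0.10 in the double mutant against swr1∆ at 37 °C, and intron 3 of SPAC11E3.10 −0.26 in prp16DAmP between temperatures.

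A replicate block within temperature gave 1 call in swr1∆ at 37 °C, 4 for pht1∆ prp16DAmP against prp16DAmP and 32 for swr1∆ between temperatures. A replicate block within the pair, where the numbers pair the arrays, gave 0 against usp107DAmP, 0 against prp16DAmP, and 2 introns and 243 transcripts for swr1∆ against pht1∆ at 30 °C. No other count moved by over 1.5 times under a block. A robust and trended prior gave 7 for the interaction at 30 °C and 8 transcripts in the double mutant at 37 °C. To remove an offset shared by all comparisons with wild type, the mean of other groups was added to the interactions. With those without a deletion they were called for 13 introns at 30 °C, 31 at 16 °C and 78 at 37 °C, and with all 7 other groups for 3, 51 and 28, but the 7 include deletions whose own effect is then added back. With the sign of the swr1∆ 37 °C arrays turned, 1 intron differed from the double mutant, 150 differed between temperatures, and 8 transcripts rose and 45 fell. Of 362 list tests 13 passed with the preset correlation and 0 with the estimated one, and 34 passed fry, which tests for any change of a list and not against other genes. For values without a test, only moves by more than the SD between replicates are given. The mean over introns in place of the median so moved 1 difference in the index of all introns, that of pht1∆ prp16DAmP and pht1∆, from −0.00915 to −0.0320.

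By the same bound, differences between tertiles of intron properties moved where the intron feature alone was used. By length they became −0.00336 in pht1∆ at 30 °C, 0.0289 in prp16DAmP at 16 °C, 0.00126 in pht1∆ prp16DAmP and −0.00398 in prp16DAmP at 37 °C. By 5′ splice site they became −0.00430 in pht1∆ usp107DAmP and −0.00262 in pht1∆ prp16DAmP. By branch site they became 0.00870 in pht1∆ usp107DAmP, −0.00056 in prp16DAmP at 16 °C, −3.2e-05 in pht1∆ prp16DAmP, −0.00492 in the double mutant at 37 °C and 0.0161 in swr1∆ at 30 °C. By distance from branch site to 3′ splice site they became −0.0268 in pht1∆ at 30 °C, −0.0536 in pht1∆ at 16 °C (from −0.0773), 0.00391 in prp16DAmP at 16 °C (from −0.0106), −0.00260 in pht1∆ prp16DAmP, 0.00468 in swr1∆ at 37 °C, −0.00545 in prp16DAmP at 37 °C and −0.00430 in swr1∆ at 30 °C. Split at the median, the differences by branch site became −0.0143 in pht1∆ usp107DAmP, −0.00807 in prp16DAmP at 16 °C and −0.0134 in pht1∆ prp16DAmP, by length −0.0779 in pht1∆ at 16 °C and 0.00232 in prp16DAmP at 37 °C, and by distance −0.0275 in pht1∆ at 30 °C, −0.0445 at 16 °C and 0.00055 in pht1∆ usp107DAmP (from −0.00951).

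Each of the 30 arrays was left out in turn. The index counts ran from 526 to 955 in pht1∆ at 30 °C, 155 to 778 in usp107DAmP, 599 to 1612 in their double mutant, 603 to 1311 in pht1∆ at 16 °C, 114 to 977 in prp16DAmP at 16 °C and 192 to 940 in their double mutant. They ran from 0 to 7 in swr1∆, 1 to 5 in prp16DAmP and 0 to 62 in the double mutant at 37 °C, and 43 to 565 in swr1∆ at 30 °C. At 30 °C differences ran from 370 to 1087 (double against pht1∆), 0 to 143 (against usp107DAmP), 8 to 33 (interaction) and 2 to 46 (swr1∆ against pht1∆). At 16 °C they ran from 255 to 766 (double against pht1∆), 0 to 14 (against prp16DAmP) and 35 to 204 (interaction). At 37 °C they ran from 1 to 218 (double against swr1∆), 0 to 3 (against prp16DAmP) and 0 to 59 (interaction). Between temperatures they ran from 189 to 580 in pht1∆, 7 to 204 in swr1∆ and 3 to 88 in prp16DAmP. Transcript counts ran from 856 to 1493 in pht1∆ at 30 °C, 293 to 1261 in usp107DAmP, 1111 to 2513 in their double mutant, 539 to 1193 in pht1∆ at 16 °C, 186 to 1074 in prp16DAmP at 16 °C and 309 to 1388 in their double mutant. They ran from 6 to 76 in swr1∆, 0 to 11 in prp16DAmP and 0 to 123 in the double mutant at 37 °C, 53 to 597 in swr1∆ at 30 °C, and 88 to 189 for swr1∆ against pht1∆. List tests past the threshold ran from 11 to 30.

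Among named introns and genes, 301 values lost their call and 3 gained a call when 1 array was left out, while 1214 kept direction and call. Fits on only the groups compared ended 116 named calls, junction features as the reference 74, exon and junction features 47, both arrays with the most repeated values left out 23, the robust prior 20 and equal spread 20. Fewer ended under the size of change (13), the blocks within the pair (12) and within temperature (9), the removed offset by all 7 groups (8) and by those without a deletion (4), centring (1) and the introns with repeated values left out (1). Named genes that kept their call without any of their own arrays include bud20 intron 1, SPAC186.08c intron 1, ers1 intron 8 and rpc82 intron 1 in pht1∆ and swr1∆ at 30 °C.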

Other observations

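The test by length of intron was chosen only after the data were seen. In pht1∆ at 16 °C weak 5′ splice sites and long introns both went with more risen indices, so the splice sites were compared within each tertile of length. Among introns up to 49 bases the index rose in 17.3% of those with a weak site (108 of 626) and 13.4% of those with a strong site (45 of 336), an odds ratio of 1.35 (Fisher's exact test, adjusted p = 0.139). Among introns up to 71 bases and longer than 49 the shares were 27.8% (145 of 522) and 20.4% (77 of 377), an odds ratio of 1.5 with adjusted p = 0.0183. Among introns of 72 bases and over they were 33.9% (116 of 342) and 23.5% (120 of 511), an odds ratio of 1.67 with adjusted p = 0.00307. Whether the odds ratios differ between lengths was not tested.

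Some arrays ran against each other over all features. Replicate 3 of swr1∆ at 37 °C correlated with replicates 1 and 2 of swr1∆ prp16DAmP with r of −0.53 and −0.44, and with replicates 1 and 2 of pht1∆ prp16DAmP with r of −0.48 and −0.41. Replicate 2 of swr1∆ at 37 °C had r of −0.42 and −0.35 with the same swr1∆ prp16DAmP arrays. The labels give the same dyes for all of these arrays, so the direction was kept. Counts with the swr1∆ 37 °C sign turned are given above.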
